A study of Mus musculus with 3 samples.

How the data were processed

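Livers of 3 mice were measured by single-cell RNA sequencing, 1 mouse and 1 library in each of the groups PBS, native MSC and engineered MSC. Per the submitters' processing notes, cells were released with enzymes at 37 °C, strained and freed of red blood cells by lysis, libraries were made with 10x 3' v3.1 chemistry and sequenced on a NovaSeq, and reads were aligned to GRCm39 and counted with Cell Ranger 7.1.0. The authors deposited filtered matrices of raw counts, in UMIs per gene and barcode, with 34099 genes in each. The values in the matrices are whole counts, and the lowest total in a barcode is 500 UMIs in each library. No authors' clustering or cell labels were used here.

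Cells were kept with at least 200 genes, at least 500 UMIs and at most 20% of UMIs from mitochondrial genes. The limit on genes removed 70, 1135 and 296 barcodes of PBS, native MSC and engineered MSC, and the mitochondrial limit covered 289, 167 and 852. Doublets were scored with Scrublet in scanpy 1.11.5, and the highest scores in each library were removed at a rate of 0.8% per 1000 barcodes, which took 923, 1054 and 973 barcodes. The 3 libraries were clustered together on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden method at resolution 1 (leidenalg 0.10.2, igraph 0.11.9). Variable genes were chosen within libraries, and no correction between libraries was made. A cluster was scored for each of 26 marker lists by the mean log2 ratio of its marker levels to those of all other cells. It took the name of the highest list if the score was at least 0.5, at least 0.5 above the best list of another lineage, and at least 3 markers were more than 1.5 times as high as in the other cells. It also had to have no more markers of another class than of its own among its 10 leading genes. A cluster with none of its own markers among these 10 and a median of UMIs more than 3 times below that of its libraries was not named, although 3 such clusters scored high enough. Cell classes are named as resembling a type, since no protein was measured. All other clusters stayed unnamed. The injected MSCs were not identified, since no cluster met the rule for mesenchymal stromal cells.

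Shares are percentages of kept cells with exact binomial (Clopper-Pearson) 95% intervals, and immune classes alone served as a second base. UMIs were summed over the cells of a class in a library and scaled to the class total as CPM, with exact Poisson 95% intervals. Ratios have exact conditional binomial 95% intervals. A gene with 0 counts in 1 library is given as a bound over a floor of 3 counts. Classes of 1 lineage with at least 100 cells in each library were compared within, which made 8 classes. Cycling cells, which mix lineages, were not compared within. The stellate and NK or ILC1 classes were smaller and their lists are not compared. With 1 library per group, no p-value, standard error or count of changed genes is given. UMIs correct for amplification, and free RNA in the droplets was not subtracted, so the medians for transcripts of hepatocytes, red cells and neutrophils are given beside the classes.

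Gene lists, classes, markers and the rule for the genes named in the report were fixed before the data were examined. The value of a list is the median log2 ratio over its members with at least 20 UMIs in the pair of libraries, with 0.5 in place of a count of 0. Its percentile comes from 10000 random lists, in which each member is replaced by one of the 100 genes nearest in expression. Intervals of list medians come from 1000 redraws of the counts. The makeup of a pair of livers is compared as the percentage of cells that would have to change class. Genes were named by a rule in neutrophil-like, macrophage-like and monocyte-like cells, up to 30 for each comparison. A gene needed at least 50 UMIs and 50 CPM in the higher library, a level in the class at least 0.5 times that in the other cells of that library, and an interval bound more than 1.5 times from equality, and the 5 with the furthest bound in each direction were taken. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, free hepatocyte, sex-linked and unnamed predicted genes were not eligible. Up to 4 members of each list with the largest ratios, and S100a8, S100a9, Cxcr2, Selp, Sele, Icam1, Cxcl1 and Cxcl2, were named as well.

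The ratios, intervals and random lists were tested on simulated data drawn at the depths of the neutrophil-like and macrophage-like classes, with 200 genes changed in each of 6 comparisons. The intervals held the true ratio for 95.0% of changed genes, and from 4.40% to 6.50% of random lists fell outside the central 95%. Counts were drawn independently for each gene from the Poisson law that the intervals assume, so these rates check the calculation only. They are no reference for how many lists of real genes lie outside the central 95%. Alternatives were at least 500 genes or 300 UMIs per cell, a mitochondrial limit of 10% or none, doublets kept, Leiden resolution 0.5 or 2, and each library clustered on its own. Others were immune classes as the base, a count of cells with at least 4 of 11 neutrophil markers after thinning each cell to 500 UMIs, and each cell counted alike as counts per 10000. The rest were median-ratio scaling, a class total without mitochondrial, haemoglobin and free hepatocyte genes, a minimum of 100 UMIs or none for list members, and ranking by the ratio itself. The closing section gives their effect. Computation used python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.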

Results

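Paracetamol (acetaminophen, APAP) in overdose kills hepatocytes around the central veins of the liver, and neutrophils enter the injured tissue before monocyte-derived macrophages clear it. Single-cell RNA sequencing (10x 3' chemistry, which counts transcripts by unique molecular identifiers, UMIs) was done on mouse liver taken 4 days into such an injury. Mice had 500 mg/kg of paracetamol and at 6 h an infusion of PBS, of native mesenchymal stromal cells (MSCs), or of MSCs engineered to carry bispecific polyvalent peptides. Each of the 3 groups is 1 library from 1 mouse, so there is no spread between animals, no test was made, and each interval covers counting error only. The PBS library held 82247448 UMIs in 10739 barcodes, the native MSC library 84950721 in 11479, and the engineered MSC library 62564254 in 11028. After filtering, 9534, 9175 and 9131 cells were kept, with a median of 5781, 5659 and 3668 UMIs per cell. Below, a value for a class is its share of kept cells with an exact binomial 95% interval, or its CPM, from the UMIs of a gene summed over the class and scaled to the class total.

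Clusters were named by marker genes as resembling a class, and the 3 libraries held them in unlike proportions. Shares are of recovered cells, and no number of cells per liver was measured. Digestion and dissociation set the yields of hepatocytes and endothelial cells. Megakaryocyte-or-platelet-like cells were 3 in native MSC, 21 in engineered MSC and 0 of 9534 in PBS, which allows a share of up to 0.0315% at 3 counts, or 0.0387% by the exact interval. In the PBS liver, myeloid cells made up most of the cells. Monocyte-like cells were 27.1%, macrophage-like cells 20.1%, endothelium-like cells 11.2%, Kupffer-cell-like cells (the resident macrophages of the liver) 7.24% and neutrophil-like cells 6.42%. In the native MSC liver, monocyte-like cells (29.7%) and neutrophil-like cells (26.8%) together formed the larger part. In the engineered MSC liver, endothelium-like (19.3%), hepatocyte-like (18.1%), B-cell-like (17.6%) and T-cell-like cells (12.6%) were the most abundant. Clusters without a name held 3.32% of PBS, 1.70% of native MSC and 6.76% of engineered MSC cells. To turn the class makeup of one liver into that of another, 50.2% of cells would have to change class between engineered MSC and PBS, 33.9% between native MSC and PBS, and 55.6% between engineered and native MSC.

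**Figure D1:**
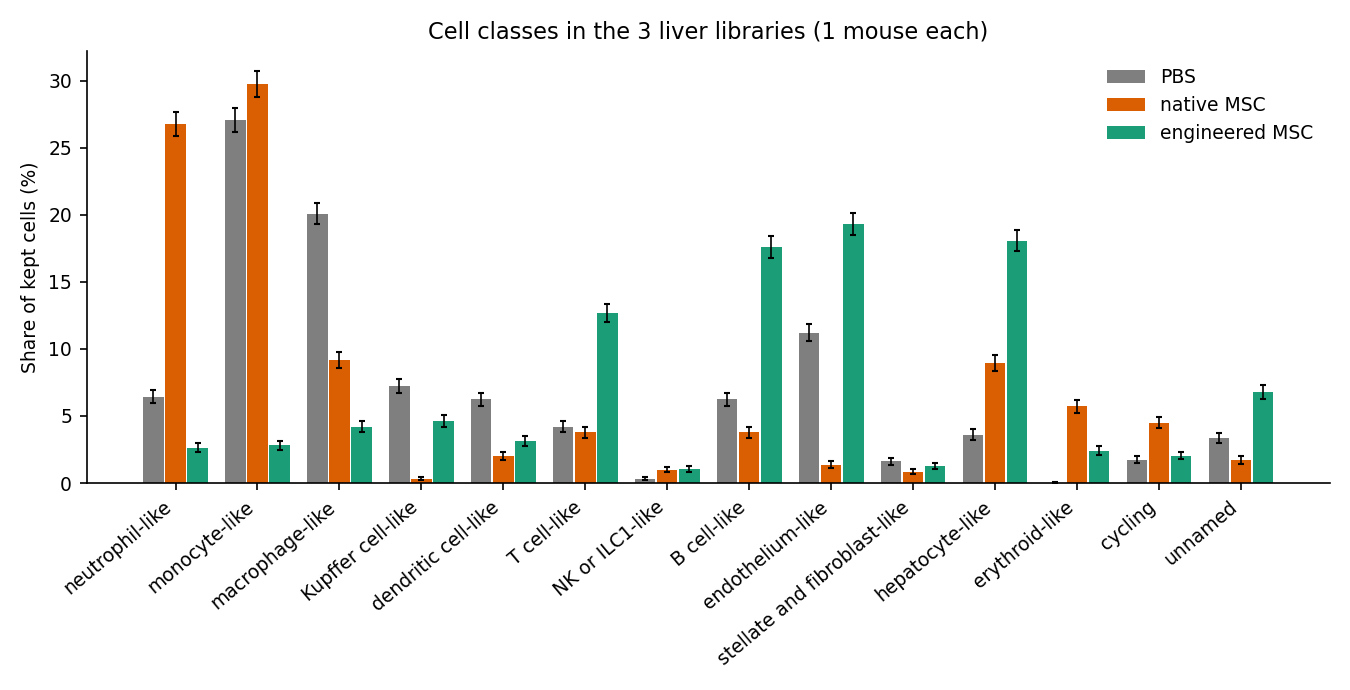
Share of kept cells (%, vertical axis) in each named class for the PBS, native MSC and engineered MSC libraries (1 mouse each); bars are shares and black lines exact binomial 95% intervals. Neutrophil-like cells are 6.42%, 26.8% and 2.63% in that order, while hepatocyte-like cells are 3.61%, 8.95% and 18.1%.

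The first comparison, engineered MSC against PBS, asks whether the engineered cells lower the number of neutrophils that stay in the injured liver and what else differs in its cells. Neutrophils, monocytes and macrophages were a smaller part of the engineered MSC liver, and hepatocytes, endothelium and lymphocytes a larger part. Its endothelium, macrophages and T cells had higher interferon response genes, and its hepatocytes higher pericentral and lower oxidative stress genes. Clusters 4, 5 and 7 held 1592 B-cell-like, 1510 hepatocyte-like and 1400 endothelium-like cells of engineered MSC, against 1, 1 and 0 of PBS. Most dendritic-cell-like cells of both libraries lay in cluster 14. A shift of the engineered MSC library as a whole was not tested, and it cannot be told apart from changes within the classes. Neutrophil-like cells were 2.63% (2.31 to 2.98) of the engineered MSC cells, 240 in number, against 6.42% (5.94 to 6.93) in PBS, 612 in number. That is a share 2.44-fold lower, a ratio of 0.409 (0.351 to 0.476). Monocyte-like cells, which enter from blood and turn into macrophages, had a share 9.65-fold lower (8.48 to 11.01), with 2.80% against 27.1%. Macrophage-like cells were 4.79-fold lower (4.29 to 5.36), with 4.19% against 20.1%. Dendritic-cell-like cells were 2.00-fold lower. Kupffer-cell-like cells were 1.57-fold lower as named, with 421 cells against 690. Cluster 25, which scored highest for Kupffer cells (2.14) but had no name because its hepatocyte score was close (1.67), held a further 264 engineered MSC cells against 1 in PBS, so this difference rests on the naming. Hepatocyte-like cells were 5.01 times as frequent (4.46 to 5.64), T-cell-like cells 3.00 times (2.68 to 3.37), B-cell-like cells 2.82 times (2.56 to 3.101) and endothelium-like cells 1.72 times (1.60 to 1.86). Cluster 21, which had no name, scored highest for sinusoidal endothelium (1.93). It held 287 PBS cells against 25 of engineered MSC, so the endothelium-like ratio would be lower with it. NK-or-ILC1-like cells were 1.04% against 0.336%, and plasma-cell-like cells were 3.92 times as frequent. Erythroid-like cells were 2.41% of engineered MSC cells against 2 PBS cells, a ratio of 115 (31.4 to 954). As a share of immune cells alone, neutrophil-like cells were 5.33% against 8.23%, a ratio of 0.647 (0.555 to 0.753). On that base the log2 ratio was -2.61 for monocyte-like, -1.60 for macrophage-like, -0.34 for dendritic-cell-like and 0.010 for Kupffer-cell-like cells, so that no Kupffer-cell-like difference was seen. It was 2.25 for T-cell-like and 2.16 for B-cell-like cells. At Leiden resolution 2 the log2 ratio of hepatocyte-like shares was 5.86 in place of 2.33, and with at least 500 genes per cell that of erythroid-like shares was 2.46 in place of 6.84.

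Neutrophils of the engineered MSC liver held more transcript of granule proteins that are made late in bone marrow maturation, and less of the cytokine genes of activated tissue neutrophils. Most of the engineered MSC neutrophil-like cells lay in cluster 32 (65.8%) and cluster 3 (26.7%), and the PBS cells in cluster 3 (89.2%). In the specific and gelatinase granule list, 6 of 8 genes were higher, with a median log2 ratio of 1.94, above all 10000 random lists of like expression. Counting each cell alike lowered this median to 0.94. Camp, the cathelicidin of the specific granule, had 422 UMIs against 0, at least 281-fold higher over a floor of 3 counts. Cluster 39, with Camp, Ngp and Ltf among its leading genes, had no name and is not part of the class. It held 24 PBS, 12 native MSC and 34 engineered MSC cells, so the count of 0 covers only the named PBS cells. No comparison within 1 cluster was made for engineered MSC. Ngp was 473 times as high (130 to 3918), Ltf 8.14 times and Mmp8 6.09 times. S100a8 (ENSMUSG00000056054) and S100a9 (ENSMUSG00000056071), whose products form calprotectin, were 2.18 times (2.13 to 2.24) and 2.13 times (2.09 to 2.17) as high. Cxcr2 (ENSMUSG00000026180), the chemokine receptor that brings neutrophils into tissue, was at 710 CPM against 678, a ratio of 1.05 (0.934 to 1.17). Azurophil granule genes, of which 2 were measured, had a median of 0.61, with Prtn3 at 2.67 times (1.18 to 6.18).

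Inflammatory cytokine and chemokine genes were lower in the same neutrophil-like cells for 11 of 13 genes, with a median of -0.60 at percentile 0.01. Ccl4 was 3.35-fold lower, Ccl3 3.07-fold lower, Il1a 3.50-fold lower and Cxcl10 2.78-fold lower. Cxcl2 (ENSMUSG00000058427), a ligand of Cxcr2, was 1.51-fold lower. Chn2, Cacnb2 and Ccrl2, the last a chemerin-binding receptor, were 6.61-fold, 5.92-fold and 3.25-fold lower. All 11 measured genes of apoptosis and survival were lower, with a median of -0.51 at percentile 0.41, and all 12 measured interferon response genes were higher, with a median of 0.35 at percentile 99.2. Inside the central 95% of random lists were the lists for mature and aged neutrophils (0.00), recruitment and adhesion receptors (0.12), the NADPH oxidase (-0.33), chromatin release (0.26, or 1.00 without a minimum count), dissociation stress (-0.19) and hypoxia and glycolysis (0.08). Icam1 (ENSMUSG00000037405), which marks aged or activated neutrophils, was 2.76-fold lower. Cyp3a11 at 108 times (51.8 to 270), Mup7 at 117 times (39.5 to 575) and Cyp2c29 with 66 UMIs against 0, at least 44.0-fold higher, are hepatocyte genes. A list of abundant hepatocyte transcripts, set up to watch for free RNA and called free hepatocyte transcripts without their source being known, had a median of 4.01 in these cells.

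Macrophages of the engineered MSC liver had higher MHC class II genes, for antigen presentation, and lower lipid-associated macrophage genes. They lay in cluster 8 (95.6%), and the PBS macrophage-like cells in cluster 1 (96.8%). All 7 MHC class II genes were higher, with a median of 1.67 (2.35 with each cell counted alike), and Ciita, their master regulator, was 6.92 times as high (5.01 to 9.59). H2-Eb1 was 3.65 times, H2-Ab1 3.35 times and H2-Aa 3.18 times as high. Ly6a was 11.6 times (10.2 to 13.2), the endothelin receptor Ednrb 9.64 times, Plac8 6.73 times, S100a4 6.55 times and F13a1 6.28 times (5.88 to 6.72) as high. Pcdh7 was 51.7-fold lower (22.1 to 159), the elastase Mmp12 9.14-fold (8.44 to 9.91), the eosinophil-associated ribonuclease Ear2 8.68-fold, the collagenase Mmp13 8.41-fold and the interleukin 1 antagonist Il1rn 7.57-fold lower. With each cell counted alike, the log2 ratios were 2.67 for Ednrb, 2.03 for S100a4, 2.03 for F13a1 and -2.07 for Mmp13, and with doublets kept that of Plac8 was 2.11. Neutrophil chemoattractants were higher for 8 of 10 genes, with a median of 1.36. Cxcl3 was 19.0 times (14.5 to 25.3), Ppbp 4.35 times, C3 3.66 times and Ccl3 3.21 times as high, and Cxcl2 was 1.36 times as high. Ppbp is also a platelet gene, and whether Ppbp and C3 came from free RNA was not tested. S100a8 and S100a9 had ratios of 0.832 (0.589 to 1.15) and 0.709 (0.521 to 0.946). Cxcl1 (ENSMUSG00000029380), another ligand of Cxcr2, was 1.92-fold lower. Inflammatory cytokines had a median of 0.72, with Il12b at 5.60 times (3.51 to 8.94), and all 14 interferon response genes were higher, with a median of 0.50. Cell cycle genes had a median of 1.68, or 0.70 with doublets kept. Cycling cells formed a class of their own, whose share had a ratio of 1.18 (0.955 to 1.47). The cell cycle medians here and below therefore cover only cells outside that class.

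Lipid-associated macrophage genes, which phagocytes turn on while digesting dead cells, were lower in engineered MSC macrophage-like cells for 9 of 10 genes, with a median of -0.37 at percentile 0.12. Lpl was 3.16-fold, Cd63 2.58-fold and Cd9 2.39-fold lower. Efferocytosis genes, for the uptake of dying cells, were lower for 9 of 12, also with a median of -0.37, with Nr1h3 2.81-fold and Mfge8 2.47-fold lower. The alternative activation and repair list had a median of -0.06, and within it Cd163 was 5.74 times and Chil3 5.71 times as high. Chil3 is also a monocyte marker, as are F13a1 and Plac8, which were higher in the same cells. Whether cells closer to monocytes account for this was not tested. Hypoxia and glycolysis genes had a median of -0.31, and oxidative stress (-0.02), dissociation stress (0.07) and NADPH oxidase genes (0.20) lay inside the random range. Free hepatocyte transcripts had a median of 3.42 and free red cell transcripts 4.46. Monocyte-like cells lay in cluster 33 (62.9%) and cluster 0 (26.2%) for engineered MSC and in cluster 0 (60.3%) and the patrolling monocyte cluster 12 (26.1%) for PBS. Their higher genes were hepatocyte transcripts, Cyp3a11 at 59.5, Mug1 at 26.0, Vtn at 20.2, Apob at 18.9 and Kng1 at 13.03 times, and the log2 ratio of Mug1 was 4.03 in place of 4.70 with each cell counted alike. Their lower genes were Bach2 (3.72-fold), Acp5 (3.72-fold), Tgm2 (2.75-fold), Cx3cr1 (2.74-fold) and Itgb5 (2.57-fold), of which the fractalkine receptor Cx3cr1 and Itgb5 are leading genes of cluster 12, with 4.30% of the engineered MSC monocyte-like cells. S100a8 and S100a9 were 7.01 times (6.54 to 7.51) and 5.76 times (5.33 to 6.23) as high in these monocyte-like cells. Cxcl1 was 2.37 times as high in monocyte-like cells (1.90 to 2.92), a direction that turned to a log2 ratio of -1.67 at the 10% mitochondrial limit.

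Endothelium of the engineered MSC liver had an interferon signature and fewer chemokine transcripts. Its cells lay in cluster 7 (79.5%) and those of PBS in cluster 9 (95.9%), both sinusoidal by their markers. Cluster 23, which scored highest for vascular endothelium and has Selp, Wnt2 and Rspo3 among its leading genes, held 13.7% of the engineered MSC but 2.81% of the PBS endothelium-like cells. All 14 interferon response genes were higher, with a median of 1.40, and 11 of them were more than 2-fold higher. Ifit3 was 7.65 times (6.15 to 9.61), Ifit1 6.61 times and Ifit2 6.35 times as high. Neutrophil chemoattractants were lower for 7 of 9 genes, with a median of -2.08, which was -0.62 with doublets kept and -0.49 without a minimum count. Cxcl2 was 6.17-fold lower in endothelium-like cells, Ccl4 4.78-fold and Mif 4.72-fold lower, while C3 was 6.77 times as high. Whether this C3 came from free RNA was not tested. Selp (ENSMUSG00000026580), or P-selectin, on which neutrophils roll, was 2.73 times as high (2.51 to 2.98). Icam1, to which they adhere, was 1.91 times as high (1.71 to 2.13), and Sele (ENSMUSG00000026582), or E-selectin, was 1.27-fold lower. The 7 measured endothelial adhesion genes had a median of -0.18. Angiocrine genes, through which liver endothelium acts on hepatocyte growth and zonation, had a median of 0.53 at percentile 99.2. Wnt2 was 8.47 times (7.57 to 9.49), Wnt9b 6.85 times and Rspo3 5.58 times as high, and Apln 16.3-fold lower. Hypoxia and glycolysis genes were lower for 10 of 11, with a median of -1.44. Scavenger receptors (0.28), dissociation stress (0.01) and cell cycle genes (-0.21, or 0.39 with doublets kept) lay inside the random range. Free hepatocyte transcripts had a median of 3.48, free red cell transcripts 5.42 and free neutrophil transcripts -1.15, the last 0.16 with doublets kept.

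Hepatocyte-like cells of the engineered MSC liver held more transcript of the pericentral enzymes that paracetamol injury removes, and less of the stress genes. They lay in cluster 5 (91.5%) and the PBS hepatocyte-like cells in cluster 11 (91.9%). Mitochondrial transcripts were a median of 0.600% of UMIs in the former and 0.176% in the latter, against 4.49% and 3.44% in endothelium-like cells. Whether these barcodes were intact hepatocytes was not tested. Cluster 11 had a hepatocyte score of 1.20, against 2.90 for cluster 5 and 2.59 for cluster 20. At Leiden resolution 2 the log2 ratio of hepatocyte-like shares was 5.86, so the naming of the PBS cells depends on the setting. Genes were not compared within classes at that setting, and the ratios below rest on this naming. All 7 measured pericentral genes were higher, with a median of 2.38 (2.30 with Axin2, at 30 UMIs against 0, at its bound). Cyp2e1, which turns paracetamol into its toxic product, was 18.0 times (12.9 to 25.7) and Glul, the glutamine synthetase of the cells next to the central vein, 5.21 times as high (3.93 to 7.06). Periportal genes were higher for 8 of 9, with a median of 0.50, and Pck1 was 3.74 times as high. Oxidative stress genes were lower for 8 of 9, with a median of -2.29. Gsta1 was 10.2-fold, Hmox1 6.15-fold, Srxn1 5.88-fold and Nqo1 5.40-fold lower. Chemoattractants had a median of -1.24, with Cxcl1 6.47-fold, Cxcl2 4.87-fold and Il1b 3.98-fold lower, while the neutrophil transcripts S100a8 and S100a9 had ratios of 2.19 (1.06 to 5.24) and 0.921 (0.647 to 1.34) there. Cell cycle genes were higher for 7 of 8, with a median of 1.49, and Ccnb2 was 11.4 times as high (3.83 to 55.9). Acute phase genes had a median of -0.05 that turned to 0.21 with median-ratio scaling, although Saa2 was 3.00 times and Saa1 2.16 times as high. Dissociation stress genes had a median of -1.10.

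T cells of the engineered MSC liver also had higher interferon genes, while the B-cell median lay inside the random range. T-cell-like cells lay in cluster 18 (44.3%) and cluster 16 (42.2%), against cluster 13 (66.4%) and cluster 16 (31.1%) in PBS, and all 13 measured interferon response genes were higher in them, with a median of 0.53. Genes of type 17 and gamma-delta T cells had a median of 0.93, with Il17a, which drives neutrophil recruitment, at 3.09 times (1.35 to 8.71). Cluster 40, with Trdc, Il23r and Il17a among its leading genes, held 3.20% of engineered MSC and 2.49% of PBS T-cell-like cells. Naive and central T-cell genes were lower for all 7, with a median of -0.40. Cytotoxicity genes had a median of 0.14, with Gzmb at 1.96 times, and regulatory genes -0.11. Cell cycle genes had a median of 1.92 in T-cell-like cells (1.71 with zero counts at their bound, 1.19 at a minimum of 100 UMIs). B-cell-like cells lay in cluster 4 (99.1%), against cluster 10 (99.8%) in PBS. Their medians were 0.24 for the interferon response (-0.36 with doublets kept), -0.02 for MHC class II, 1.26 for the cell cycle (1.22 at the bound) and -0.33 for dissociation stress, which was -0.40 in T-cell-like cells. Free hepatocyte transcripts had a median of 3.98 in both classes, free neutrophil transcripts -0.13 in T-cell-like and -0.15 in B-cell-like cells, and free red cell transcripts 4.54 (3.98 at the bound) and -0.03. With doublets kept, free neutrophil transcripts were at -1.10 and -1.26 in T-cell-like and B-cell-like cells, and free red cell transcripts at 8.91 and 4.26 there, 6.24 in macrophage-like and 3.89 in endothelium-like cells. In this comparison 37 of 61 lists lay outside the central 95% of random lists.

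**Figure D2:**
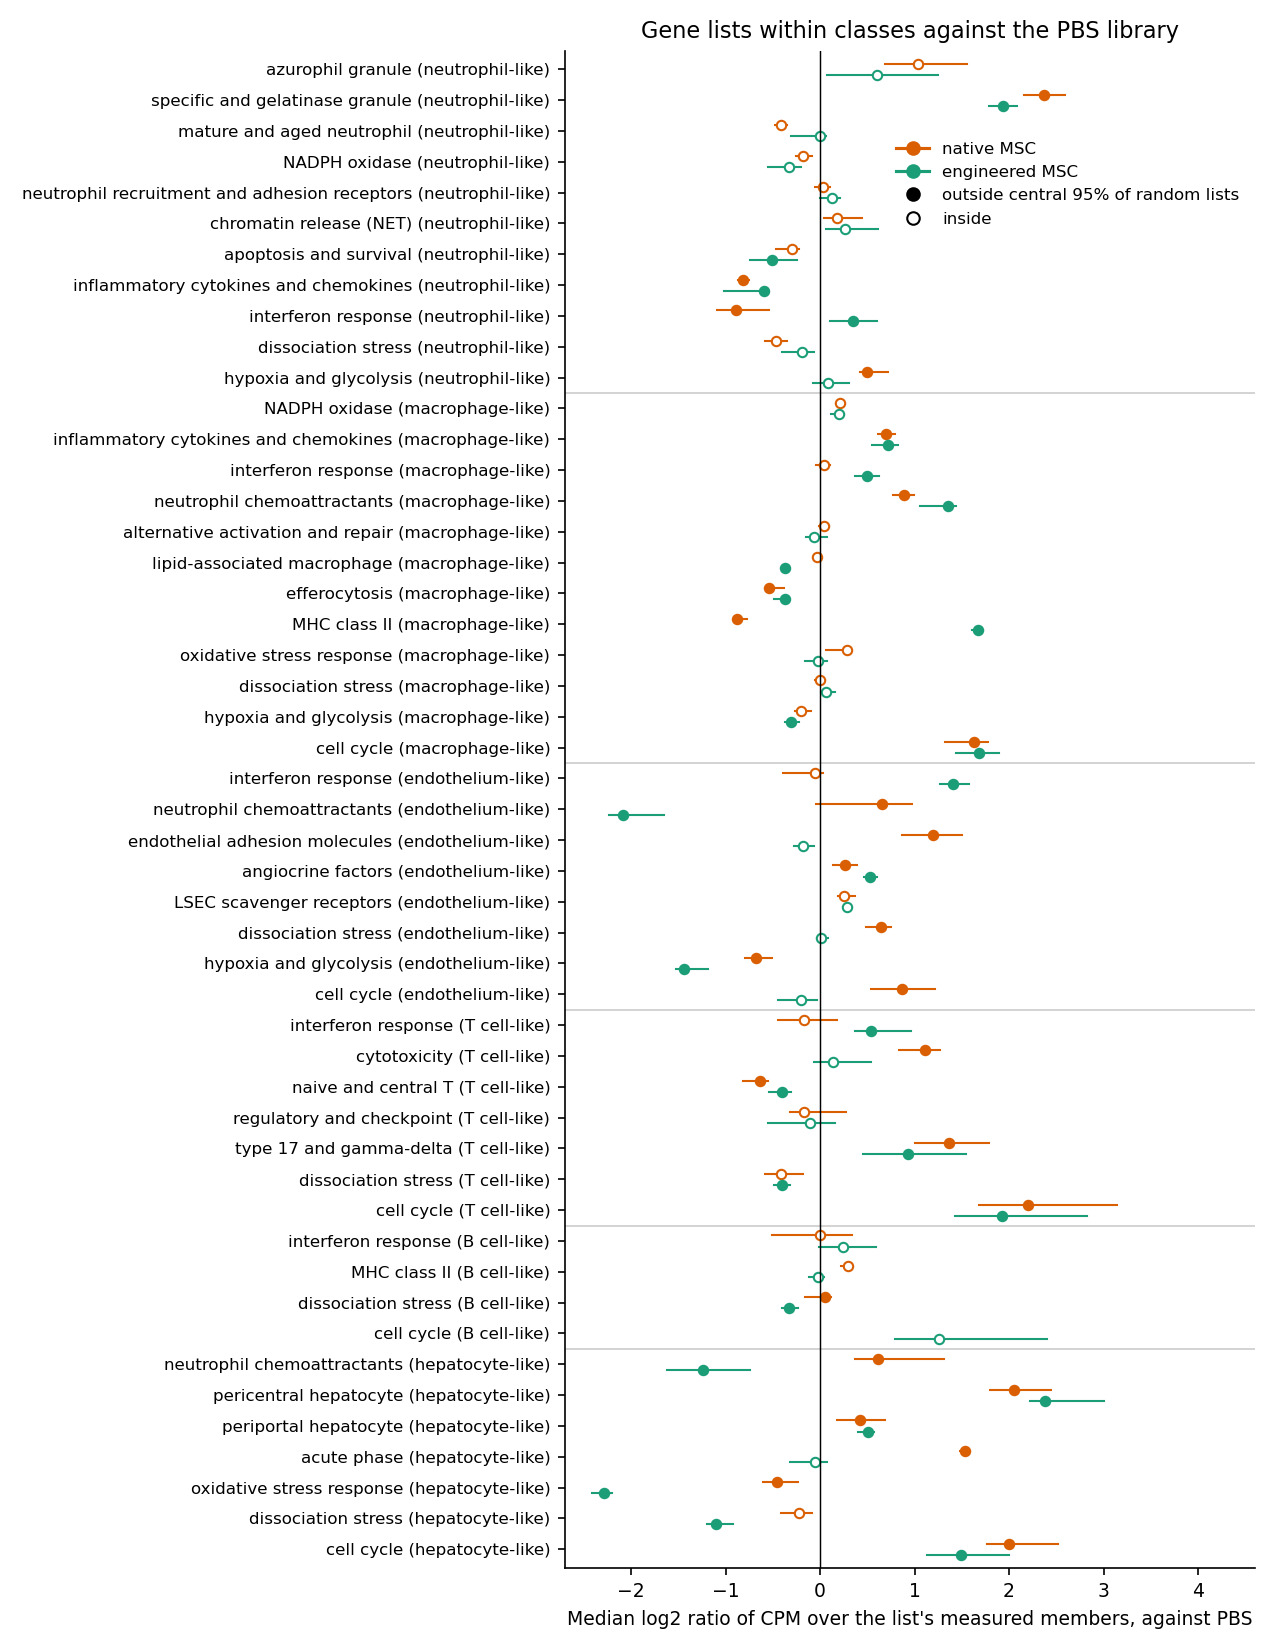
Median log2 ratio of CPM against PBS (horizontal axis) over the measured members of each gene list in each class, for native and engineered MSC (1 mouse each); lines are 95% intervals from redrawn counts, filled points lie outside the central 95% of random lists, and the lists of free RNA are not drawn. MHC class II in macrophage-like cells has a median of 1.67 for engineered and -0.88 for native MSC, and the interferon response in endothelium-like cells 1.40 and -0.05.

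The next comparison, native MSC against PBS, asks what the carrier cells do without the peptides. Neutrophils and cycling cells were a larger part of the cells recovered from its liver than in PBS, and endothelial cells and resident macrophages a smaller part. Its hepatocytes had higher acute phase genes, its endothelium higher adhesion genes and its neutrophils lower interferon response genes. Neutrophil-like cells were 26.8% (25.9 to 27.7) of native MSC cells, 2455 in number, against 6.42%, a ratio of 4.17 (3.81 to 4.56). As a share of immune cells they were 34.9% against 8.23%. With each library clustered on its own the log2 ratio was 1.20 in place of 2.06. Kupffer-cell-like cells were 0.316% against 7.24%, a share 22.9-fold lower (15.8 to 34.4). Endothelium-like cells were 8.16-fold lower (6.78 to 9.89), dendritic-cell-like cells 3.07-fold, macrophage-like cells 2.19-fold (2.02 to 2.38), stellate-and-fibroblast-like cells 1.90-fold and B-cell-like cells 1.65-fold lower. With doublets kept the log2 ratio of stellate-and-fibroblast-like cells was -1.74 in place of -0.93. With each library clustered on its own the log2 ratios were -2.25 for Kupffer-cell-like cells in place of -4.52 and -0.30 for macrophage-like cells in place of -1.13, and at Leiden resolution 2 it was -3.88 for Kupffer-cell-like cells. Hepatocyte-like cells were 2.48 times as frequent (2.18 to 2.82), a log2 ratio of 1.31 that was 3.34 at Leiden resolution 2 and 2.15 with each library clustered on its own. Cycling cells were 2.62 times (2.18 to 3.16) and NK-or-ILC1-like cells 2.96 times as frequent. Erythroid-like cells were 5.71%, a ratio of 272 (75.0 to 2254) to the 2 PBS cells. T-cell-like cells had a ratio of 0.894 (0.772 to 1.04). Monocyte-like cells had a ratio of 1.10 (1.04 to 1.16), which turned to a log2 ratio of -0.52 with at least 500 genes per cell.

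Neutrophils of the native MSC liver comprised a part rich in granule transcripts and a part that clustered with the PBS neutrophils. The native MSC neutrophil-like cells lay in cluster 6 (54.3%) and cluster 3 (45.4%). Both clusters scored highest for neutrophils (4.45 and 2.12) and not for their precursors. In all of them, the specific and gelatinase granule list was higher for 7 of 8 genes, with a median of 2.37. That median was 0.96 with each cell counted alike and 0.05, at percentile 54.9, in cluster 3 alone, a comparison chosen after the clusters were seen. Camp had 2649 UMIs against 0 in PBS, at least 150-fold higher, of which 8 UMIs were in cluster 3. Cells of the unnamed cluster 39, which Camp leads, are again not counted here. Ngp was 413 times (114 to 3413), the stefin Stfa2 111 times (51.0 to 303), the prokineticin Prok2 69.9 times (23.9 to 339) and Cstdc5 32.5 times (21.7 to 51.4) as high. S100a8 was 3.00 times (2.94 to 3.06) and S100a9 2.81 times (2.77 to 2.85) as high. In cluster 3, with 1115 native MSC and 546 PBS cells, the S100a8 ratio was 0.585 (0.567 to 0.603), the S100a9 ratio 0.641 (0.628 to 0.653) and that of Cxcr2 0.689 (0.630 to 0.755). Over all neutrophil-like cells, the Cxcr2 ratio was 1.01 (0.939 to 1.08). Calprotectin transcripts were also found in T-cell-like cells, with S100a8 at 134 CPM in native MSC against 9.19 in PBS, and their source there was not tested.

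Interferon response genes were lower in the native MSC neutrophil-like cells for 11 of 12, with a median of -0.89, below all 10000 random lists. In cluster 3 alone the median was -1.47. Rsad2, the antiviral enzyme viperin, was 5.51-fold lower, or 10.5-fold in cluster 3, and Ifit3 was 4.11-fold lower. The PD-1 ligand Cd274 was 4.70-fold, Chn2 5.62-fold, Ccl4 4.45-fold and the growth factor Csf1 4.32-fold lower, and in cluster 3 these were 4.91-fold, 3.36-fold, 2.68-fold and 2.10-fold lower. Inflammatory cytokines were lower for 10 of 14 genes, with a median of -0.82, or -0.14 in cluster 3, while Nos2 was 12.8 times as high (4.34 to 62.7). Hypoxia and glycolysis genes had a median of 0.50 at percentile 99.9. Medians were 1.04 for azurophil granules (1.69 without a minimum count, with Prtn3 at 5.13 times), -0.42 for mature and aged neutrophils, where Cxcr4, the receptor of aged cells, was 2.82-fold lower, and -0.18 for the NADPH oxidase. They were 0.04 for recruitment receptors, 0.18 for chromatin release (0.99 without a minimum count), -0.30 for apoptosis and survival and -0.46 for dissociation stress. Among the receptors, Ltb4r1, which senses leukotriene B4, was 4.00 times (3.17 to 5.12) and Fpr1, which senses formyl peptides, 2.23 times as high. Icam1 was 2.46-fold lower in neutrophil-like cells and Cxcl2 had a ratio of 0.998. Free hepatocyte transcripts had a median of 1.63 and free red cell transcripts 7.36 (7.33 at the bound), or 6.59 with each cell counted alike.

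Macrophages of the native MSC liver, in cluster 8 (96.8%), had lower antigen-presenting and efferocytosis genes than those of PBS. The MHC class II list was lower for 5 of 7 genes, with a median of -0.88 at percentile 0.06. H2-Aa was 2.16-fold and H2-Eb1 1.92-fold lower. Ednrb was 16.6 times (13.9 to 20.0), F13a1 10.2 times, S100a4 9.83 times, Ly6a 9.62 times and Eps8 5.79 times as high. Mmp12 was 15.9-fold (14.8 to 17.1), Pcdh7 20.2-fold, Adcy3 9.46-fold, the adhesion molecule Vcam1 9.34-fold and Apbb2 8.96-fold lower, with a log2 ratio for Pcdh7 of -4.99 in place of -4.34 when each cell counted alike. Spp1, which encodes osteopontin, was 4.09 times as high (4.06 to 4.13), while the lipid-associated list around it had a median of -0.03. Efferocytosis genes were lower for 11 of 12, with a median of -0.54, and Mfge8 was 4.38-fold, Nr1h3 3.30-fold and the phagocytic receptor Axl 3.20-fold lower. Chemoattractants had a median of 0.89, with Cxcl3 at 14.1 times and Ppbp, also a platelet gene, at 11.1 times, and inflammatory cytokines 0.70. The neutrophil transcripts S100a8 and S100a9 were 10.4 times (9.12 to 11.95) and 12.1 times (10.9 to 13.5) as high in the same cells. Cxcl2 was 1.73 times as high in macrophage-like cells, and Cxcl1 was 1.42-fold lower, turning to a log2 ratio of 0.16 with each cell counted alike. Within alternative activation (0.04), Chil3, which like F13a1 is also a monocyte marker, was 13.4 times and Cd163 4.02 times as high. Other medians were 0.04 for the interferon response, 0.28 for oxidative stress, 0.21 for the NADPH oxidase, -0.00 for dissociation stress, -0.20 for hypoxia and glycolysis and 1.63 for the cell cycle (0.61 with doublets kept). The median of free hepatocyte transcripts was 1.65 and that of free red cell transcripts 7.29.

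Monocyte-like cells lay in cluster 2 (52.2%), cluster 0 (38.8%) and the patrolling cluster 12 (8.94%) for native MSC, against 13.5%, 60.3% and 26.1% in PBS. The chemokine Ppbp was 26.5 times as high in them (20.2 to 35.4), Lrg1 9.21 times (8.21 to 10.4), Cxcl3 6.92 times (6.33 to 7.58), Pf4 4.39 times and Mmp8 3.51 times. S100a8 and S100a9 were 5.95 times (5.66 to 6.26) and 4.87 times (4.62 to 5.14) as high in the same cells. Ppbp and Pf4 are also platelet genes, and at the 10% mitochondrial limit their log2 ratios were 3.56 in place of 4.73 and 1.16 in place of 2.13. Hes1 was 5.24-fold, the MHC class II chain Cd74 4.78-fold (4.61 to 4.95), Bach2 4.16-fold, Grk3 3.69-fold and Hivep3 3.58-fold lower. Cxcl1 was 1.68 times and Cxcl2 1.26 times as high in monocyte-like cells.

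Endothelium of the native MSC liver, 126 cells, had higher adhesion genes. It lay in cluster 9 (63.5%), sinusoidal by its markers, and in the vascular cluster 23 (27.0%), which has Selp among its leading genes and held 2.81% of the PBS endothelium-like cells. Endothelial adhesion genes were higher for 6 of 7, with a median of 1.20. Selp was 6.32 times (5.68 to 7.03), Icam1 4.27 times (3.71 to 4.92) and Sele 2.29 times (1.84 to 2.85) as high, and with each cell counted alike the log2 ratio of Selp was 3.35 in place of 2.66. Cd34 was 3.32 times as high. Chemoattractants had a median of 0.66, with Cxcl2 at 2.42 times (2.07 to 2.81) and Il1b at 3.19 times, and the median turned to -0.11 with each cell counted alike. Angiocrine genes had a median of 0.27 at percentile 98.1, with Wnt9b at 11.2 times, Rspo3 at 8.68 times, Apln 6.30-fold lower and Angpt2 4.34-fold lower. Hypoxia and glycolysis genes had a median of -0.68, the interferon response -0.05, scavenger receptors 0.25, dissociation stress 0.65 and the cell cycle 0.87 (2.10 with doublets kept). Free neutrophil transcripts had a median of 2.55 in endothelium-like cells, free hepatocyte transcripts 1.38 and free red cell transcripts 8.56.

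Hepatocyte-like cells of the native MSC liver had higher acute phase genes than those of PBS. They lay in cluster 11 (62.2%) and cluster 20 (37.6%). Cluster 20, with Saa1, Saa2, Orm2 and Orm1 among its leading genes, held 7.85% of the PBS hepatocyte-like cells. Mitochondrial transcripts were a median of 0.0837% of UMIs in native MSC hepatocyte-like cells, and whether these were intact hepatocytes was not tested. The PBS side rests on cluster 11 (91.9%), with its lower hepatocyte score (1.20). Whether a PBS class poor in hepatocyte transcripts adds to the ratios below was not tested. All 12 acute phase genes were higher, with a median of 1.54, and the serum amyloid genes Saa2 and Saa1 were 19.6 times (17.6 to 21.9) and 16.7 times (15.2 to 18.4) as high. Pericentral genes were higher for 5 of 6, with a median of 2.06, and Cyp2e1 was 6.90 times as high. Periportal genes had a median of 0.43, with Ass1 at 2.79 times and Pck1 at 2.16 times. Oxidative stress genes had a median of -0.46 at percentile 1.33, with Srxn1 2.65-fold and Gsta1 2.02-fold lower. Chemoattractants had a median of 0.62, with Il1b at 4.33 times and Cxcl2 at 3.20 times, both also neutrophil transcripts. S100a8 and S100a9 were 36.6 times (18.5 to 84.9) and 14.7 times (10.7 to 20.7) as high in the same hepatocyte-like cells. All 8 cell cycle genes were higher, with a median of 2.00, and Ccnb2 was 24.5 times as high (8.29 to 119). Dissociation stress had a median of -0.23. T-cell-like cells, in cluster 13 (86.1%), had higher cytotoxicity genes for 8 of 9, with a median of 1.11 and the granzymes Gzmb at 4.85 times and Gzmk at 3.40 times. Type 17 and gamma-delta genes had a median of 1.36, with Il17a at 6.59 times (2.84 to 18.7), and cluster 40, which these genes lead, held 6.65% of native MSC T-cell-like cells, 23 in number, against 2.49% in PBS, 10 in number. Other T-cell medians were -0.64 for naive and central genes, -0.16 for regulatory genes, -0.17 for the interferon response, -0.42 for dissociation stress and 2.20 for the cell cycle. B-cell-like cells, in cluster 10 (99.1%), had medians of 0.29 for MHC class II, 0.00 for the interferon response and 0.056 for dissociation stress, the last turning to -0.089 with doublets kept. Free neutrophil transcripts had medians of 3.61 and 3.53 in T-cell-like and B-cell-like cells (1.57 and 2.64 with doublets kept), free hepatocyte transcripts 1.44 and 2.10, and free red cell transcripts 11.47 (10.82 at the bound) and 4.16. Red cell transcripts with doublets kept were at 7.57 in B-cell-like and 5.54 in endothelium-like cells, where neutrophil transcripts were at 3.25. In this comparison 39 of 61 lists lay outside the central 95% of random lists.

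**Figure D3:**
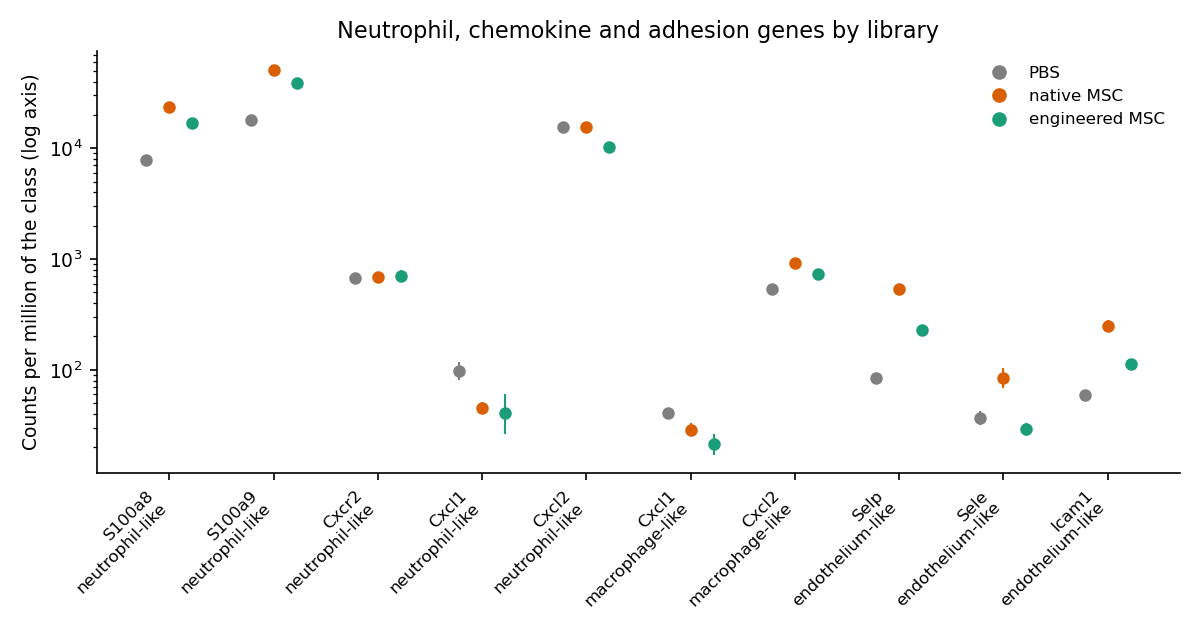
CPM (log axis) of neutrophil, chemokine and adhesion genes in the named class for PBS, native MSC and engineered MSC (1 mouse each); points are values and vertical lines exact Poisson 95% intervals. Cxcr2 in neutrophil-like cells is 678, 683 and 710 CPM, while Selp in endothelium-like cells is 84.1, 532 and 230 CPM.

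The comparison of engineered with native MSC asks what the peptides add to the cells that carry them. Neutrophils and monocytes were less frequent in the engineered MSC liver, its macrophages had higher antigen-presenting genes, and its endothelium had lower adhesion genes. The neutrophil-like share was 10.2-fold lower (8.91 to 11.7) and the monocyte-like share 10.6-fold lower. On immune cells alone the log2 ratio for neutrophil-like cells was -2.71 in place of -3.35, and with each library clustered on its own it was -2.43. Endothelium and resident macrophages went the other way. Kupffer-cell-like cells were 14.6 times (10.0 to 22.1) and endothelium-like cells 14.1 times (11.7 to 16.97) as frequent. With each library clustered on its own, the log2 ratio of Kupffer-cell-like cells was 2.08 in place of 3.87 and that of monocyte-like cells -4.08 in place of -3.41. B-cell-like cells were 4.66 times (4.15 to 5.25), T-cell-like cells 3.35 times (2.97 to 3.79), hepatocyte-like cells 2.02 times (1.86 to 2.20) and dendritic-cell-like cells 1.54 times (1.28 to 1.86) as frequent. For the last pair, the log2 ratios with each library clustered on its own were 0.29 in place of 1.01 and 0.02 in place of 0.62. At Leiden resolution 2 they were 3.14 for Kupffer-cell-like and 2.52 for hepatocyte-like cells. Macrophage-like cells were 2.18-fold, cycling cells 2.21-fold and erythroid-like cells 2.37-fold lower. With at least 500 genes per cell the erythroid-like log2 ratio was -4.52 in place of -1.25. On immune cells alone the log2 ratio was -0.49 in place of -1.13 for macrophage-like cells, -2.77 for monocyte-like, 4.503 for Kupffer-cell-like, 1.26 for dendritic-cell-like, 2.38 for T-cell-like and 2.86 for B-cell-like cells.

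Interferon response genes separated the engineered from the native MSC liver in 4 classes. Most engineered MSC neutrophil-like cells (cluster 32, 65.8%) and endothelium-like cells (cluster 7, 79.5%) lay apart from those of native MSC, while macrophage-like cells shared cluster 8. No correction between libraries was made, and a shift of the engineered MSC library as a whole was not tested. In neutrophil-like cells 11 of 12 were higher, with a median of 1.24, and Ifit3 was 6.91 times and Rsad2 5.83 times as high. The median was 1.88 in endothelium-like cells, where Ifit1 was 11.1 times as high (5.07 to 30.4), 0.86 in T-cell-like and 0.46 in macrophage-like cells. In B-cell-like cells it was 0.23, inside the random range. The granule list had a median of 0.18 in neutrophil-like cells, where Camp was 1.87 times as high and Lcn2 2.31-fold lower, and the azurophil list -0.43. The S100a8 ratio was 0.727 (0.713 to 0.741) and Cxcl2 was 1.51-fold lower. The stefin genes Stfa3, Stfa2 and Stfa1 were 21.9-fold (7.46 to 106), 5.64-fold and 4.81-fold lower, and Cstdc5 and Id1 3.90-fold and 3.56-fold lower. The higher genes were hepatocyte transcripts, Mup7 at 43.9, Cyp2d9 at 23.2, Ugt2b5 at 19.9, Mug1 at 15.2 and Scd1 at 12.8 times. Hypoxia and glycolysis genes had a median of -0.50 at percentile 0.01. Other neutrophil medians were 0.12 for mature and aged cells (Cxcr4 at 2.07 times), 0.09 for recruitment receptors (Ltb4r1 2.96-fold lower), -0.20 for the NADPH oxidase, 0.05 for chromatin release, -0.17 for apoptosis and survival, -0.06 for inflammatory cytokines (Nos2 4.81-fold lower) and 0.14 for dissociation stress. Free hepatocyte transcripts had a median of 1.88 and free red cell transcripts -4.29.

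Macrophages of both MSC livers lay in cluster 8 and differed in antigen presentation. All 7 MHC class II genes were higher in engineered MSC, with a median of 2.21 (2.96 with each cell counted alike). H2-Eb1 was 7.03 times (6.51 to 7.58), H2-Aa 6.85 times, H2-Ab1 6.16 times, Cd74 4.63 times and Tmcc3 3.31 times as high. With each cell counted alike their log2 ratios were 3.57, 3.50, 3.37, 2.89 and 2.41. Il12b, a subunit of interleukin 12, was 18.0 times as high (7.098 to 58.2). Spp1 was 3.01-fold (2.97 to 3.05), Cd9 3.09-fold, the fatty acid carrier Fabp4 2.03-fold, Atp6v0d2 1.82-fold and Anxa1 1.75-fold lower. With each cell counted alike the log2 ratio was -2.34 for Spp1 and -0.23 for Atp6v0d2. Lipid-associated genes had a median of -0.25 at percentile 1.56 and efferocytosis genes 0.13, with Axl at 2.03 times and Mertk at 1.60 times. S100a8 was 12.5-fold (9.24 to 17.4) and S100a9 17.1-fold lower in these cells. Other medians were 0.05 for inflammatory cytokines, 0.04 for chemoattractants, -0.12 for alternative activation, -0.23 for oxidative stress, -0.08 for the NADPH oxidase, -0.10 for dissociation stress, -0.16 for hypoxia and glycolysis and 0.08 for the cell cycle. The median of free hepatocyte transcripts was 1.29 and that of free red cell transcripts -2.85. In monocyte-like cells Mug1 at 19.2, Cyp3a11 at 11.1, Scd1 at 8.56 and Apob at 6.94 times are hepatocyte genes, and the heat shock gene Hspa1b was 3.97 times as high. Ppbp was 2.39-fold (a log2 ratio of -1.88 at the 10% mitochondrial limit), Saa3 1.88-fold, Ccl3 1.77-fold and Chil3 1.62-fold lower, and no further gene met the rule for lower ones. Cxcl1 was 1.41 times as high there, turning to a log2 ratio of -2.00 at the 10% mitochondrial limit, and Cxcl2 1.18 times, turning to -0.15 with each cell counted alike.

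Endothelium of the engineered MSC liver had lower adhesion genes and its hepatocytes lower acute phase genes than those of native MSC. The vascular cluster 23, with Selp among its leading genes, held 13.7% of engineered MSC and 27.0% of native MSC endothelium-like cells. In endothelium-like cells all 7 adhesion genes were lower, with a median of -1.16. Sele was 2.91-fold, Selp 2.31-fold (a log2 ratio of -1.98 with each cell counted alike), Icam1 2.24-fold and Cd34 4.27-fold lower. Chemoattractants were lower there for 8 of 10, with a median of -1.53, and Cxcl2 was 14.9-fold and Il1b 14.2-fold lower, beside the neutrophil transcripts S100a8 at 13.7-fold and S100a9 at 12.4-fold lower. Other endothelial medians were -0.12 for angiocrine genes (Wnt2 at 2.07 times), 0.17 for scavenger receptors, -0.91 for hypoxia and glycolysis, -0.47 for dissociation stress and -1.23 for the cell cycle (-1.89 with doublets kept). In hepatocyte-like cells acute phase genes were lower for 11 of 12, with a median of -2.07, and Orm2 was 11.8-fold, Lcn2 10.0-fold, Saa1 7.74-fold and Saa2 6.53-fold lower. Cluster 20, which Saa1 and Saa2 lead, held 2.06% of engineered MSC and 37.6% of native MSC hepatocyte-like cells. Oxidative stress genes had a median of -1.93 (-1.05 with each cell counted alike), with Mt1 5.86-fold and Gsta1 5.04-fold lower. Chemoattractants had a median of -1.64 (-0.88 without a minimum count), with Il1b 17.2-fold, Cxcl2 15.6-fold and Cxcl1 6.15-fold lower. In the same hepatocyte-like cells S100a8 was 16.7-fold (13.3 to 21.1) and S100a9 15.9-fold (13.6 to 18.7) lower. Pericentral genes had a median of 0.43, with Glul at 5.39 times, and periportal genes 0.37. Dissociation stress was at -0.70 and the cell cycle at -0.76. In T-cell-like cells the medians were -0.84 for cytotoxicity, with Gzmb 2.47-fold lower, 0.21 for naive and central genes, -0.16 for regulatory genes, -0.23 for type 17 and gamma-delta genes (-0.85 with each cell counted alike), 0.01 for dissociation stress and -0.19 for the cell cycle. In B-cell-like cells they were -0.35 for MHC class II, -0.20 for dissociation stress and 0.56 for the cell cycle. Free neutrophil transcripts had medians of -3.74 in T-cell-like, -3.68 in B-cell-like and -3.71 in endothelium-like cells. Those of free hepatocyte transcripts were 1.86, 1.57 and 1.97, and those of free red cell transcripts -6.60, -4.18 and -3.22. With doublets kept the red cell medians were -2.57, -3.32 and -1.64, and -1.30 in macrophage-like cells, and the neutrophil medians -2.67 in T-cell-like and -3.10 in endothelium-like cells. In this comparison 34 of 62 lists lay outside the central 95% of random lists.

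All ratios within classes are scaled to the class total. Scaling by the median ratio in its place moved the median of all genes by more than 0.1 in 7 comparisons. In hepatocyte-like cells it went from -0.10 to 0.15 for engineered MSC against PBS and from -0.25 to -0.01 for native MSC against PBS. For native MSC against PBS it also went from -0.01 to 0.10 in neutrophil-like, from -0.18 to -0.04 in monocyte-like, from -0.14 to 0.06 in T-cell-like and from -0.13 to -0.03 in B-cell-like cells. In T-cell-like cells it went from 0.15 to -0.00 for engineered against native MSC.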

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

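Tests of the base of the neutrophil share and of blood left in the liver were chosen only after the result was seen. At the settings used above, the results here went in opposite directions in engineered and native MSC against the same PBS library, and these differences between the groups were not tested, since each group is 1 mouse. Neutrophil-like shares had ratios to PBS of 0.409 for engineered and 4.17 for native MSC, and monocyte-like shares 0.104 and 1.10. B-cell-like shares had ratios of 2.82 and 0.604, and endothelium-like shares 1.72 and 0.123. Interferon response genes in neutrophil-like cells had medians of 0.35 for engineered and -0.89 for native MSC. MHC class II genes in macrophage-like cells had medians of 1.67 and -0.88. Neutrophil chemoattractants had medians of -2.08 and 0.66 in endothelium-like cells and of -1.24 and 0.62 in hepatocyte-like cells. Dissociation stress genes in B-cell-like cells were at -0.33 and 0.056, and free neutrophil transcripts in endothelium-like cells at -1.15 and 2.55. In 4 of these pairs a setting brought both to the same direction. They are monocyte-like shares with 500 genes (-0.52 for native MSC), endothelial chemoattractants with each cell counted alike (-0.11), B-cell dissociation stress with doublets kept (-0.089) and endothelial free neutrophil transcripts with doublets kept (0.16 for engineered MSC).

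Other signals came from barcodes as deposited, before filtering, and from clusters without a name, whose genes were not compared. Barcodes with more than 50% of UMIs from haemoglobin genes, as in red cells, made up 13.7% of barcodes in native MSC and 3.21% in engineered MSC, against 0.140% in PBS. The limit on genes removed 1109 of the 1572 such barcodes in native MSC and 132 of the 354 in engineered MSC. The mitochondrial limit covered 7.73% of engineered MSC barcodes, against 2.69% in PBS and 1.45% in native MSC. Of the clusters without a name, cluster 22 held 3.20% and cluster 25 held 2.89% of engineered MSC cells, and cluster 35 held 1.28% of native MSC cells. Their highest marker scores were for hepatocytes (3.26) in cluster 22, for Kupffer cells (2.14) in cluster 25 and for monocytes (0.888) in cluster 35.

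As a share of kept cells and of immune cells, neutrophils were most frequent in native MSC and least frequent in engineered MSC. The tables argue against dilution by hepatocytes and endothelium as the whole cause. On immune classes alone the ratio was 0.647 (0.555 to 0.753) for engineered MSC against PBS and 4.24 (3.88 to 4.64) for native MSC against PBS. This base still holds lymphocytes, and B-cell-like and T-cell-like cells of engineered MSC had ratios to PBS of 4.46 and 4.74 on it. The ratios of monocyte-like (0.164) and macrophage-like cells (0.33) were below that of neutrophil-like cells, and those of dendritic-cell-like (0.792) and Kupffer-cell-like cells (1.01) above it. The 240 engineered MSC neutrophil-like cells stood beside 256 monocyte-like and 383 macrophage-like cells, and the 612 of PBS beside 2579 and 1915. Relative to monocyte-like and macrophage-like cells, neutrophil-like cells were thus more frequent in engineered MSC than in PBS. Relative to dendritic-cell-like and Kupffer-cell-like cells they were less frequent, so the direction depends on the base. No base without lymphocytes was used, and dilution by them cannot be told apart from a lower number of neutrophils. Blood left in the native MSC liver could have brought neutrophils with the red cells. The prediction written for it was a cluster 3 share no higher than in PBS and a higher B-cell-like share. Neither was seen, since neutrophil-like cells of cluster 3 were 2.12 times as frequent (1.91 to 2.36) and B-cell-like cells were lower, at 0.604. Blood still cannot be told apart, because the blood counts of these mice were not analysed here, so no value forbids it. A loss of RNA-poor neutrophils under the limit on UMIs cannot be told apart either, since all barcodes have at least 500 UMIs and the ratio of shares under 1000 UMIs, engineered over native MSC, was 0.778 (0.304 to 1.67). An effect of the infused cells on neutrophil entry remains open and untested with 1 mouse in each group, as do differences between mice in injury or handling.

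Hepatocyte transcripts were higher in every class of engineered MSC cells compared with PBS, among neutrophil-like, macrophage-like, T-cell-like, B-cell-like and endothelium-like cells. Doublets with hepatocytes are argued against, since the 5% of B-cell-like cells with most of these transcripts held 13.9% of them. Free RNA from hepatocytes may be the source, as 99.7% (99.3 to 99.9) of engineered MSC B-cell-like cells had at least 1 such UMI after thinning to 500 UMIs, against 65.0% in PBS and 89.3% in native MSC. The level of such RNA may follow the number of hepatocytes that entered or broke in the suspension, and that was not tested.

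Macrophages of PBS lay in cluster 1, and those of both MSC livers in cluster 8. A shift of all classes of the PBS library could produce this, and it cannot be told apart from a change in the macrophages, because genes far apart in native MSC and PBS macrophages also differed elsewhere. There were 36 such genes, of which 25 were measured in T-cell-like, 24 in B-cell-like and 34 in endothelium-like cells. Of the median log2 ratio of the measured genes in macrophage-like cells, 35.2%, 45.9% and 39.9% was found in these classes. Engineered MSC was not used, so a shift of the native MSC library would give the same picture. Neutrophil transcripts were not barred from these genes, and free neutrophil transcripts had native MSC medians of 3.61, 3.53 and 2.55 in the same classes. PBS and native MSC had the same main cluster for B-cell-like (10), T-cell-like (13), hepatocyte-like (11), endothelium-like (9) and dendritic-cell-like cells (14). They had unlike main clusters for neutrophil-like, monocyte-like and Kupffer-cell-like cells, so these libraries were parted in some classes and not in others. A response of macrophages to infused stromal cells of either kind stays open and untested, since the PBS group is 1 mouse.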

How the results depend on the processing

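The comparison within 1 neutrophil cluster was chosen only after the result was seen, and the causes of the moves below were not tested unless named. In all 10 settings tried for it, the neutrophil-like share kept its order of native MSC, PBS and engineered MSC. None of these settings left lymphocytes out of the base. On immune classes its log2 ratio was -0.63 for engineered MSC against PBS and -2.71 for engineered against native MSC. With each library clustered on its own it was 1.20 for native MSC against PBS and -2.43 for engineered against native MSC, as 1058 native MSC neutrophil-like cells became unnamed. The percentage of cells that would change class between engineered MSC and PBS was 52.9 at the 10% mitochondrial limit, 53.2 without a limit, 51.5 and 53.9 at Leiden resolution 0.5 and 2, 43.7 with own clustering and 53.2 on immune classes. Between native MSC and PBS it was 30.7 at 500 genes, 36.8 at the 10% limit, 36.9 at resolution 0.5, 27.7 with own clustering and 25.03 on immune classes. Between engineered and native MSC it was 53.8 at 500 genes, 52.9 with doublets kept, 61.4 at resolution 2, 48.3 with own clustering and 62.9 on immune classes. Reversals were few. The monocyte-like share of native MSC against PBS was at -0.52 with 500 genes, where 878 cells became unnamed, and the Kupffer-cell-like share of engineered MSC at 0.010 on immune classes. Cxcl1 in monocyte-like cells was at -1.67 and -2.00 at the 10% limit, Cxcl2 there at -0.057, and Ccl21a in native MSC endothelium-like cells at 1.02 with doublets kept. With doublets kept, native MSC dissociation stress in B-cell-like cells was at -0.089 and engineered MSC free neutrophil transcripts in endothelium-like cells at 0.16. With each cell counted alike, Cxcl1 in native MSC macrophage-like cells was at 0.16, Cxcl2 in monocyte-like cells at -0.15, native MSC endothelial chemoattractants at -0.11 and B-cell dissociation stress at -0.026. Of the other values, 215 of 1296 for lists, 191 of 1390 for single genes and 62 of 256 for other shares moved beyond their interval. Some of these changed sign where the list lay inside the random range or the interval held 0, as engineered MSC against PBS with doublets kept for the B-cell interferon response (-0.36) and the endothelial cell cycle (0.39). In the 1 cluster, 10 of 13 lists moved. The minimum of 300 UMIs removed nothing, as no barcode is under 500.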

Other observations

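No test here was planned, and the genes below were chosen after their values were seen. In hepatocyte-like cells of engineered MSC, the fatty acid elongase Elovl3 was 309 times (85.5 to 2553), Mup1 76.0 times (29.6 to 279), the bile acid and steroid carrier Slco1a1 76.1 times (13.6 to 3014), Hsd3b5 27.3 times (13.2 to 68.0) and the sulfotransferase Sult2a8 12.3 times (10.3 to 14.8) as high as in PBS. Against native MSC, Hsd3b5 was 70.5 times, Slco1a1 56.2 times, Elovl3 44.9 times, Sult2a8 34.8 times (30.2 to 40.3) and Mup1 28.1 times as high. The ratios of native MSC to PBS were 6.89 for Elovl3, 2.71 for Mup1, 1.35 for Slco1a1, 0.387 for Hsd3b5 and 0.353 for Sult2a8. The PBS side of these ratios rests on cluster 11, with its hepatocyte score of 1.20. The sex of the mice was not examined here, and with 1 mouse in each group a difference between mice cannot be told apart. The cornified envelope gene Sprr1a had 3 UMIs in engineered MSC against 225 in PBS, a ratio of 0.00285 (0.000583 to 0.00844), and in native MSC it was 45.3-fold lower than in PBS, or at a log2 ratio of -4.44 in place of -5.50 with doublets kept. Anxa2 was 16.98-fold lower in engineered and 4.28-fold lower in native MSC, and the keratin Krt8 11.4-fold and 4.45-fold lower. With each cell counted alike the log2 ratio of Krt8 in native MSC was -1.32 in place of -2.15. Mitochondrial transcripts were a median of 0.176% of UMIs in PBS, 0.0837% in native MSC and 0.600% in engineered MSC hepatocyte-like cells.

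Dendritic-cell-like cells differed in the genes of their subsets. Most lay in cluster 14, which held 66.0% of them in PBS, 67.2% in native MSC and 56.1% in engineered MSC. Xcr1, the receptor of cross-presenting dendritic cells, was 5.60 times (4.74 to 6.65) as high in engineered MSC as in PBS, and 3.78-fold lower in native MSC. Il12b had 512 UMIs in PBS and 0 in native MSC, and was 1.68-fold lower in engineered MSC. Ccl22, which attracts regulatory T cells, was 4.27-fold lower in engineered MSC and 10.5-fold lower in native MSC. Both are leading genes of the migratory cluster 36, which held 10.1% of the class in PBS (60 cells), 2.15% in native MSC (4 cells) and 8.42% in engineered MSC (24 cells). Retnla, a gene of type 2 immunity, had 376 UMIs in PBS, 1 in native MSC and 0 in engineered MSC. In T-cell-like cells Il4 was 4.57-fold and Zbtb16, the regulator of innate-like T cells, 2.69-fold lower in native MSC than in PBS. Both are leading genes of cluster 16, which held 31.1% of PBS but 6.65% of native MSC T-cell-like cells. Endothelium-like cells of PBS expressed more Ch25h, Esm1 and Tubb3, and lay in cluster 9 for 95.9%, against 63.5% in native MSC and 4.03% in engineered MSC. Esm1, a gene of endothelial tip cells, was 4.66-fold lower in engineered and 5.06-fold lower in native MSC. Ch25h, which makes an oxysterol, was 10.2-fold and 5.44-fold lower, and Tubb3 14.4-fold and 4.05-fold lower. The log2 ratios in engineered MSC with each cell counted alike were -4.17 in place of -3.35 for Ch25h and -4.90 in place of -3.85 for Tubb3, and in native MSC that of Ch25h was -1.79 in place of -2.44 with doublets kept.

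Cluster 35 had no name and held 119 cells, of which 117 were from native MSC. A count of cells with neutrophil markers after thinning, which needs no clusters, gave 4.87% in PBS, 21.4% in native MSC and 2.00% in engineered MSC. The order of the neutrophil-like shares was the same as with clusters. No T-cell-like, B-cell-like or endothelium-like cell among 2065 in PBS, 818 in native MSC and 4523 in engineered MSC met that count.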
